A study of Homo sapiens with 18 samples.

How the data were processed

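RNA was measured by sequencing of LNCaP libraries made from total RNA with the NEBNext Ultra kit, in 6 groups of 3. The deposited table held RPKM values for each library, made by the authors after alignment with STAR to hg38 per the submitters' processing notes. The counting program, the gene annotation and whether the libraries were stranded are not given in the sources used here. The vehicle of KC7F2, the vector backbone of the HIF1A shRNA and whether cells with 1 shRNA also received a second vector are not stated.

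Of 26475 lines deposited, 32 had no value and were left out, and 26443 genes remained, of which 23809 were matched by symbol to GENCODE 29 for position, exon length and GC content. No library was left out. Depth was recovered from the 2219 genes of up to 200 nt, whose lowest values are whole multiples of the value of 1 read. With the recovered depth, 93.5 to 96.2% of low values were whole read numbers within 2%, and depth came to 3.26 to 12.1 (in units of 1e6 reads). At these depths low genes rest on few reads, and counting error is part of the spread between replicates.

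Values were analysed as log2(RPKM + 0.5) for the 12900 genes with at least 1 RPKM in at least 3 of 18 libraries, with no further scaling. limma 3.58.1 in R 4.3.3 fitted 1 model over the 6 groups with 12 residual degrees of freedom, with eBayes and an intensity trend, two-sided. The contrasts were FOXA1 knockdown against control, HIF1A knockdown against control, KC7F2 against control, HIF1A knockdown and KC7F2 each added to FOXA1 knockdown, FOXA1 knockdown within each inhibited background, and the interactions of FOXA1 knockdown with HIF1A knockdown and with KC7F2. P-values were adjusted by Benjamini-Hochberg within each contrast and called below 0.05. The contrasts share libraries, and no adjustment was made over the 9 contrasts.

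Of 25 gene lists, the 20 with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over lists within a contrast, and again with a correlation estimated from the data and with fry. Counts adjusted over the list alone use the members only. Groups, contrasts, lists, tests, the rule for named genes and other settings of the fit were fixed before the data were examined. The rule named FOXA1 and HIF1A, the 6 largest rises and 6 largest falls with an adjusted p below 0.05, a mean of at least 2 RPKM in 1 group and no overlap between groups, and up to 4 members of each list by smallest adjusted p. It also named CCL2, VEGFA, CA9 and KLK3 in the contrasts of FOXA1 knockdown and those on top of it, and for interactions the 6 genes with the smallest adjusted p. The text prints the 12 largest changes and the first 1 to 4 members per described list in order of adjusted p, and some of these results are not reported here. Lists are described for FOXA1 knockdown in full, and elsewhere where camera called them, with hypoxia targets, glycolysis enzymes and androgen receptor targets throughout.

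Correlations of fold changes run across genes and are descriptive. For contrasts that share libraries the value from 100 simulated data sets with no effect is given beside them. The fit was tested on simulated data: in a design of the same size, changes of 1.5-fold, 2-fold and 4-fold were called in 31 of 64, 54 of 63 and 62 of 64 genes, with 6 false calls among 153.

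Other settings chosen beforehand were a pseudocount of 0.1 or 1, no filter, at least 5 RPKM in 3 libraries, median-ratio scaling, quantile normalisation, robust eBayes, only the groups compared, replicate number as a block and each library left out in turn. Added after the data were seen were removal of each library's trend on gene length and GC content, leaving out small RNA genes, a term for the kinds of length trend in the KC7F2 contrast, and leaving out the 3 libraries with more signal in short genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for annotation, depth and figures.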

Results

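Gene expression was measured by RNA sequencing in LNCaP, an established human prostate cancer cell line that carries the androgen receptor. FOXA1 is a transcription factor that opens chromatin for that receptor. The 18 libraries fell into 6 groups of 3: a control vector (pGIPZ), an shRNA against HIF1A, an shRNA against FOXA1, both shRNAs, the control vector with KC7F2 and the FOXA1 shRNA with KC7F2. Lentiviral infection lasted 5 days, and every culture received 100 µM CoCl2, a chemical mimic of hypoxia that stabilises HIF1A protein, for the last 24 h. HIF1A is the oxygen-regulated subunit of a transcription factor that turns on glycolysis and angiogenesis genes, and KC7F2, given at 40 µM for 24 h, is a small-molecule inhibitor of HIF1A. The deposited values were RPKM for 26443 genes. Library sizes were not given, but the spacing of the lowest values put them between 3.26 and 12.1 (in units of 1e6 reads), with a mean of 11.1 ± 0.678 (SD, n = 3) in control, 10.8 ± 1.67 in shHIF1A, 6.33 ± 1.28 in shFOXA1, 6.06 ± 2.61 in the doubly infected group, 10.97 ± 1.20 in control with KC7F2 and 8.22 ± 1.34 in shFOXA1 with KC7F2. Between 11589 and 11828 genes reached 1 RPKM in a library. Group levels are mean ± SD in RPKM (n = 3), and changes are log2 fold changes ± SE on the log2(RPKM + 0.5) scale, which understates the change of genes with low RPKM. Percentages left and folds are taken on that scale, not from the mean RPKM. A gene is said to rise or fall only at an adjusted p below 0.05 (limma, 12900 genes tested). For gene lists, the median log2 fold change of the tested members and the adjusted p of camera, which ranks a list against all other genes, are given. Libraries are named by group and replicate number, with KC7F2 alone for the control vector plus KC7F2. The labels state triplicates but not separate cultures, so p-values measure the spread between these samples.

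The shRNAs lowered their targets. FOXA1 mRNA (chromosome 14, 37589984 to 37596059, hg38) fell by 1.47 ± 0.16 after FOXA1 knockdown, from 97.5 ± 22.7 to 34.1 ± 1.51 RPKM, with 36.0% left (adjusted p = 3.44e-06). HIF1A mRNA (chromosome 14, 61695513 to 61748259) rose by 1.9995 ± 0.23 in the same cells, from 23.1 ± 7.91 to 89.9 ± 8.998 RPKM, 3.999-fold (adjusted p = 8.36e-06). HIF1A mRNA fell by 2.49 ± 0.23 after HIF1A knockdown, to 3.56 ± 0.642 RPKM, with 17.9% left (adjusted p = 4.97e-07), and by 4.23 ± 0.23 when the HIF1A shRNA was added to FOXA1 knockdown, to 4.32 ± 0.245 RPKM, with 5.35% left (adjusted p = 1.45e-09). With KC7F2 the change of HIF1A mRNA was -0.38 ± 0.23 in control cells (adjusted p = 0.559) and -0.52 ± 0.23 in FOXA1 knockdown cells (adjusted p = 0.275). In the other backgrounds FOXA1 mRNA fell by 0.89 ± 0.16 under HIF1A knockdown, with 53.8% left (adjusted p = 0.00109), and by 1.37 ± 0.16 under KC7F2, with 38.7% left (adjusted p = 8.94e-06). The doubly infected cells held 64.5 ± 5.77 RPKM of FOXA1 against 34.1 ± 1.51 with the FOXA1 shRNA alone, a rise of 0.91 ± 0.16 (adjusted p = 0.000302), while neither interaction on FOXA1 passed: 0.58 ± 0.22 with HIF1A knockdown (adjusted p = 0.142) and 0.11 ± 0.22 with KC7F2 (adjusted p = 0.971). HIF1A knockdown alone changed FOXA1 by 0.33 ± 0.16 (adjusted p = 0.113), which passed without control 2 (adjusted p = 0.046), and KC7F2 by 0.09 ± 0.16 (adjusted p = 0.859).

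**Figure D1:**
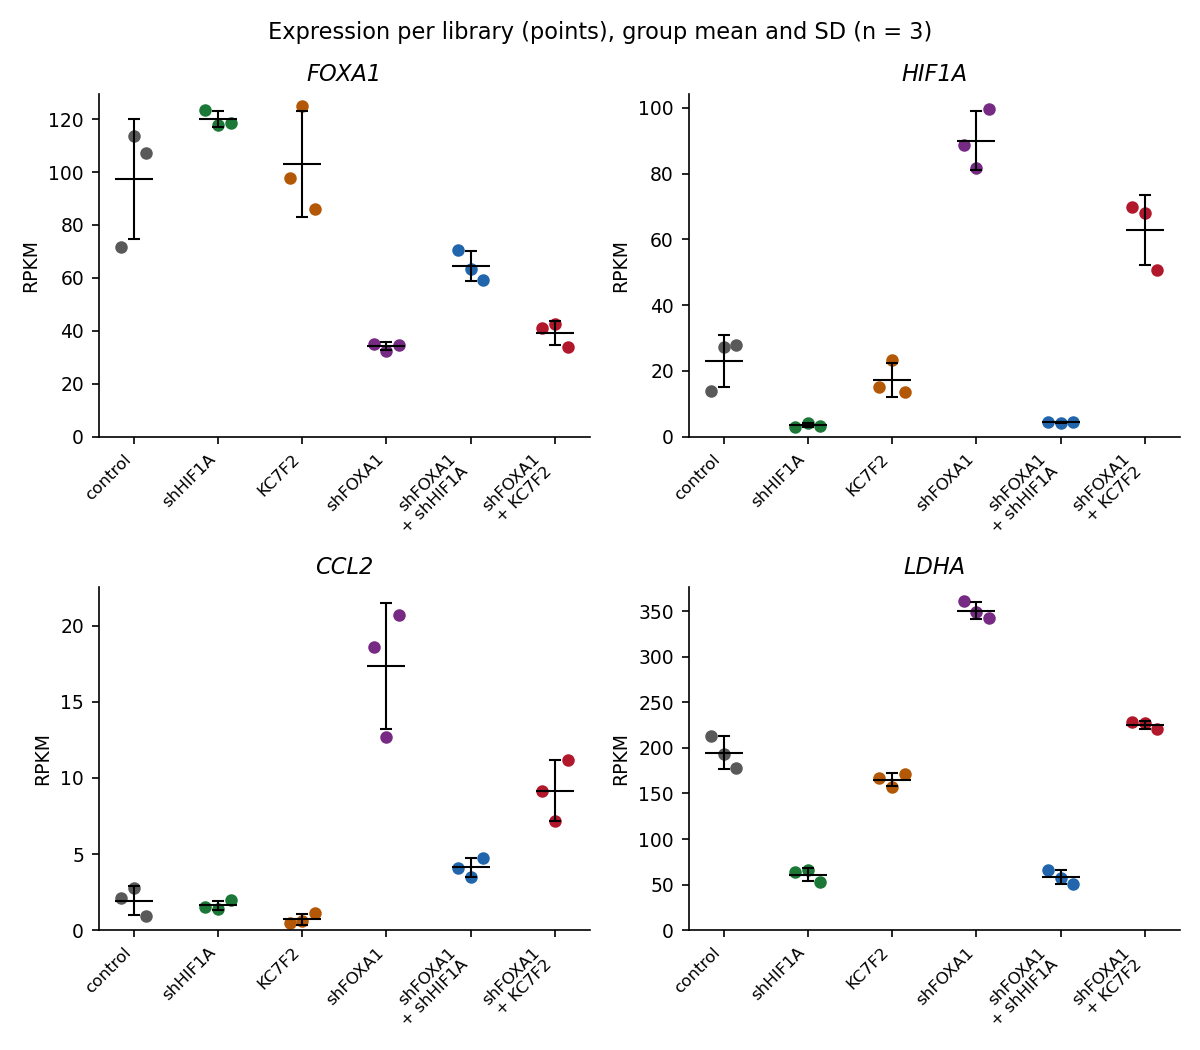
RPKM of FOXA1, HIF1A, CCL2 and LDHA in each of the 18 libraries, by group, with the mean and SD of 3 libraries. HIF1A averaged 23.1 RPKM in control, 89.9 in shFOXA1 and 4.32 in the doubly infected cells.

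FOXA1 knockdown against control asked what changes when FOXA1 is lost under hypoxia mimic. KRT16 (chromosome 17), a keratin of stressed squamous epithelium, rose by 6.25 ± 0.17, from 0.0674 ± 0.0767 to 42.6 ± 5.77 RPKM (adjusted p = 3.84e-13). The calgranulin S100A9 (chromosome 1) rose by 5.12 ± 0.20, from 0.928 ± 0.263 to 48.9 ± 5.62 RPKM, and its partner S100A8 reached 15.5 ± 4.75 RPKM from a control level listed at 0. PI3, the elastase inhibitor elafin (chromosome 20), rose by 4.84 ± 0.21, from 2.55 ± 0.275 to 87.4 ± 13.8 RPKM. PIP, a secretory protein of apocrine glands, rose by 4.49 ± 0.39, and the secreted ligand WNT11 rose by 4.44 ± 0.17. Among these 6 genes the highest adjusted p was 6.1e-07. The falls included S100P, a calcium-binding protein that fell by 4.09 ± 0.34, from 54.5 ± 21.7 to 2.85 ± 1.49 RPKM, and the androgen-regulated TARP transcript, which fell by 4.02 ± 0.21. UGT2B11, a steroid glucuronosyltransferase, fell by 3.22 ± 0.16, and SLC45A3, the luminal antigen prostein, fell by 2.95 ± 0.13 (adjusted p at most 1.52e-07). The small nucleolar RNAs SNORD28 and SNORD14E were listed at 0 after FOXA1 knockdown, against 11.5 ± 5.09 and 3.85 ± 2.54 RPKM in control (adjusted p = 0.000153 and 0.0171), and the SNORD14E call was lost without control 1 (adjusted p = 0.0586) or control 3 (0.0515), or with control 1 and KC7F2 1 and 3, which carried more signal in short genes, left out (0.0764). Reads of KRT16, KRT6A, KRT6B, UGT2B11, the TARP locus, SAA1, metallothioneins, histones, HSPA1B, FTH1 and GAPDH can be shared with close copies, and without strand information genes that lie inside others, small nucleolar RNAs and microRNAs included, are uncertain.

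Hypoxia genes rose after FOXA1 knockdown. Of the hypoxia targets, 20 of 34 rose and 1 fell (21 and 2 adjusted over the list alone), median 0.41, camera adjusted p = 5.25e-09. ERO1A, an oxidase of protein folding, rose by 1.69 ± 0.11, and the glycolytic regulator PFKFB4 rose by 1.10 ± 0.10. The glucose transporter SLC2A1 rose by 0.88 ± 0.12, with PPFIA4 at 1.38 ± 0.17 (adjusted p of these 4 at most 5.66e-05). VEGFA, the main angiogenic growth factor, rose by 0.40 ± 0.14 (adjusted p = 0.0431), and this call was lost without control 1 (adjusted p = 0.105), control 3 (0.107), shFOXA1 2 (0.106) or shFOXA1 3 (0.147), or in other settings, such as removal of the length and GC trend (0.148). CA9, a carbonic anhydrase induced by HIF1A, stayed below the level needed for a test, at 0.544 ± 0.254 RPKM against 0.139 ± 0.0995 in control. Among glycolysis enzymes, 13 of 21 rose and 3 fell (14 and 3 over the list alone), median 0.43, camera adjusted p = 3.01e-07 (adjusted p = 0.137 with an estimated correlation). The glycogen branching enzyme GBE1 rose by 1.80 ± 0.13, enolase ENO2 rose by 1.29 ± 0.11 and aldolase ALDOA rose by 0.77 ± 0.13. LDHA, which turns pyruvate into lactate, rose by 0.85 ± 0.11, from 195 ± 17.9 to 351 ± 9.39 RPKM (adjusted p of these 4 at most 0.000392). HIF pathway regulators ranked higher too: 4 of 17 rose and 1 fell (4 and 1 over the list alone), median 0.09, camera adjusted p = 0.0355 (adjusted p = 0.166 with an estimated correlation). CITED2, a HIF1A competitor, rose by 1.13 ± 0.10. The oxygen sensor EGLN1 rose by 0.64 ± 0.12 and the HIF1A paralog EPAS1 by 1.28 ± 0.19. HIF1A was the other riser. The list lost its call without control 1 (adjusted p = 0.0992) or shFOXA1 3 (0.0521), or in settings such as trend removal (0.186).

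Nuclear-encoded genes of oxidative phosphorylation ranked lower: 0 of 29 rose and 6 fell (0 and 8 over the list alone), median -0.31, camera adjusted p = 0.00291 (adjusted p = 0.57 with an estimated correlation). COX5A, of the respiratory chain, fell by 0.59 ± 0.14 and ATP5B, of ATP synthase, fell by 0.40 ± 0.10, with adjusted p at most 0.00783. Both were lost with only the groups compared (adjusted p = 0.0632 and 0.126), ATP5B with quantile normalisation (-0.19, adjusted p = 0.077), and the list call without control 1 (adjusted p = 0.134), or with the 3 libraries left out (0.106). Control 1 and the KC7F2-treated control libraries 1 and 3 carried more signal in short genes: the shortest 25% of 8627 genes exceeded the longest 25% by 0.52, 0.47 and 0.38 log2 units, against -0.19 to 0.09 in the others. They are the 3 libraries left out elsewhere. The noncoding RNA RN7SK stood at 377 ± 77.2 RPKM in shFOXA1 and 379 in control 3, against 75.3 and 96.5 in the other control libraries.

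Of the androgen receptor targets, 3 of 29 rose and 19 fell (3 and 20 over the list alone), median -0.56, camera adjusted p = 9.97e-08. ACPP, prostatic acid phosphatase, fell by 2.46 ± 0.10. The prostaglandin dehydrogenase HPGD fell by 2.14 ± 0.13 (adjusted p of both at most 4.3e-09). KLK3, which encodes prostate-specific antigen, stood at 629 ± 41.6 against 813 ± 129 RPKM, a change of -0.36 ± 0.13 (adjusted p = 0.0574), and passed without control 3 (adjusted p = 0.0212). Luminal epithelial markers split: 7 of 22 rose and 4 fell (8 and 4 over the list alone), median 0.14, camera adjusted p = 0.331. FOLH1, the prostate-specific membrane antigen, fell by 1.27 ± 0.09, and the ETS factor SPDEF fell by 1.77 ± 0.13, whereas the epithelial factor GRHL2 rose by 0.90 ± 0.12. Basal epithelial markers rose: 5 of 6 rose and 0 fell (5 and 0 over the list alone), median 1.67, camera adjusted p = 1.32e-07. The laminin subunit LAMB3 rose by 3.03 ± 0.13, and the hemidesmosome collagen COL17A1 rose by 3.21 ± 0.18. FOXA and partner transcription factors showed no common direction: 4 of 9 rose and 2 fell (5 and 4 over the list alone), median 0.29, camera adjusted p = 0.378. FOXO3 rose by 1.41 ± 0.10, ETV1 fell by 1.25 ± 0.11 and FOXA1 fell.

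Secreted immune signals rose and cell cycle genes fell. Of the chemokines and cytokines, 8 of 11 rose and 0 fell (8 and 0 over the list alone), median 1.17, camera adjusted p = 4.77e-07. CCL2, which attracts monocytes, rose by 2.93 ± 0.28, from 1.93 ± 0.946 to 17.3 ± 4.14 RPKM (adjusted p = 7.11e-07), and the neutrophil attractants CXCL2 and CXCL8 rose by 2.43 ± 0.23 and 2.28 ± 0.23, CXCL8 from 4.91 ± 1.89 to 24.5 ± 0.305 RPKM. The interferon response gave no call: 2 of 25 rose and 0 fell (2 and 0 over the list alone), median 0.06, camera adjusted p = 0.0826. OAS1 rose by 1.29 ± 0.25 and RSAD2 rose by 0.93 ± 0.22. Every tested proliferation gene fell: 0 of 30 rose and 30 fell (0 and 30 over the list alone), median -1.26, camera adjusted p = 9.98e-21. RRM2, of ribonucleotide reductase, fell by 1.97 ± 0.16, the spindle protein NUSAP1 fell by 1.66 ± 0.13 and topoisomerase TOP2A fell by 1.60 ± 0.13. Of the p53 targets, 5 of 20 rose and 0 fell (5 and 0 over the list alone), median 0.10, camera adjusted p = 0.0143 (adjusted p = 0.313 with an estimated correlation), a call lost without control 3 (adjusted p = 0.0583). The cell cycle inhibitor CDKN1A rose by 0.80 ± 0.11, and MDM2 rose by 0.59 ± 0.09. Mesenchymal markers gave 4 of 10 rose and 0 fell (4 and 0 over the list alone), median 0.06, camera adjusted p = 0.0332 (adjusted p = 0.137 with an estimated correlation), a call lost without control 1 (adjusted p = 0.0511) or shFOXA1 1 (0.0552), or in other settings, such as quantile normalisation (0.0922). The matrix protein THBS1 rose by 1.73 ± 0.14, and the repressor SNAI2 rose by 1.60 ± 0.27. In the TGF-beta pathway, 5 of 19 rose and 2 fell (6 and 2 over the list alone), median 0.07, camera adjusted p = 0.0143, lost with 5 RPKM or more (adjusted p = 0.241) or trend removal (0.0628). TGFBR2 rose by 2.25 ± 0.18, TGFB3 rose by 2.77 ± 0.23 and the decoy receptor BAMBI fell by 1.01 ± 0.14.

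Of the ATF4 and unfolded protein response genes, 3 of 28 rose and 9 fell (3 and 13 over the list alone), median -0.23, camera adjusted p = 0.0348 (adjusted p = 0.566 with an estimated correlation), a call lost without control 1 (adjusted p = 0.0896) or shFOXA1 1 (0.0817), or in other settings, such as 5 RPKM or more (0.0977). The serine synthesis enzyme PSAT1 fell by 1.01 ± 0.10 and asparagine synthetase ASNS fell by 0.72 ± 0.10. For NRF2 targets, 6 of 22 rose and 2 fell (6 and 4 over the list alone), median 0.03, camera adjusted p = 0.157, a list that passed without control 1 (adjusted p = 0.0316), or with quantile normalisation (0.0347) or the 3 libraries left out (0.0383). Haem oxygenase HMOX1 rose by 2.23 ± 0.15, and the glutathione enzyme GCLC rose by 0.72 ± 0.09. For the heat shock response, 4 of 17 rose and 2 fell (4 and 3 over the list alone), median -0.04, camera adjusted p = 0.378. Its mean was 0.17 and its median became 0.05 under median-ratio scaling and 0.01 under quantile normalisation. The small chaperone CRYAB rose by 3.76 ± 0.29. Cholesterol synthesis genes ranked lower: 0 of 21 rose and 7 fell (0 and 10 over the list alone), median -0.31, camera adjusted p = 0.00141 (adjusted p = 0.176 with an estimated correlation). SC5D fell by 0.66 ± 0.10 and HMGCS1 fell by 0.54 ± 0.09. The metallothionein list gave 0 of 5 rose and 0 fell (0 and 0 over the list alone), median -0.43, camera adjusted p = 0.458, and MT1X was at -0.57 ± 0.23 (adjusted p = 0.0798), a gene that passed without control 2 (adjusted p = 0.0298). Replication histones gave 0 of 14 rose and 1 fell (0 and 0 over the list alone), median -0.29, camera adjusted p = 0.56. In all, 1228 genes rose and 1883 fell, 369 and 324 of them at least 2-fold, and 4647 had an unadjusted p below 0.05. With median-ratio scaling 1569 rose and 1436 fell, with quantile normalisation 1534 and 1586, and with only the groups compared 761 and 986. Over the 9 contrasts camera, with its preset correlation, called 92 lists, and 38 calls held with an estimated correlation.

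**Figure D2:**
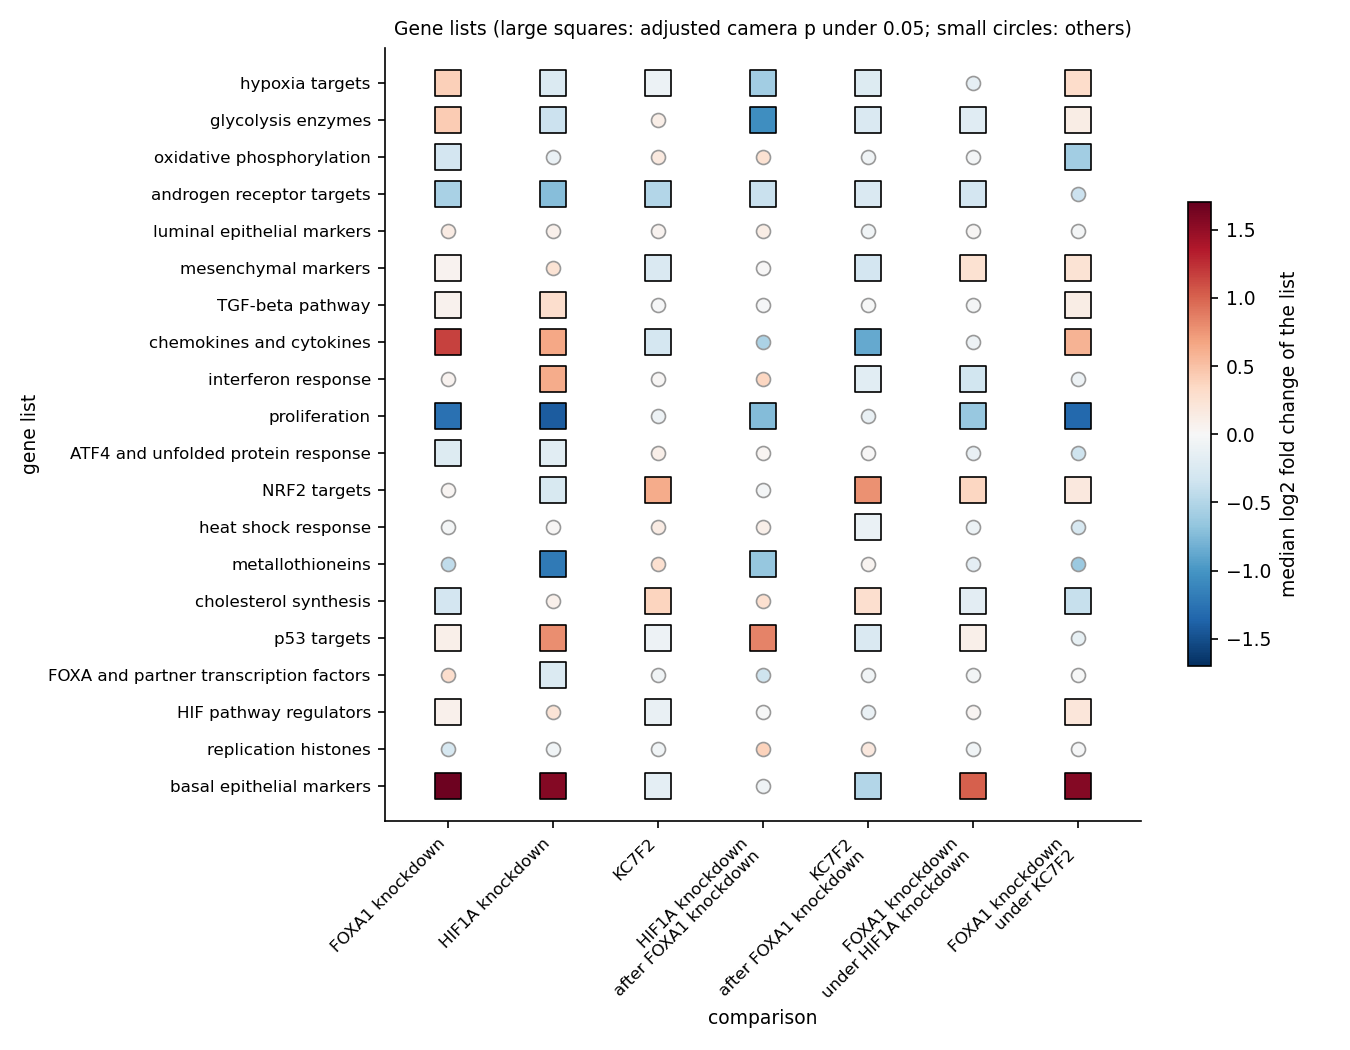
Median log2 fold change of the tested members of 20 gene lists (rows) in 7 comparisons (columns), with large squares for a camera adjusted p below 0.05. Proliferation genes had a median of -1.26 after FOXA1 knockdown and -1.42 after HIF1A knockdown.

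HIF1A knockdown against control asked what depends on HIF1A when FOXA1 is present. The collagenases MMP1 and MMP13 and the stromelysin MMP10 stood at 7.30 ± 0.721, 7.60 ± 0.450 and 11.7 ± 0.385 RPKM, with MMP1 listed at 0 in control, and MMP13 and MMP10 rose by 2.81 ± 0.22 and 3.44 ± 0.23. PI3 rose by 3.25 ± 0.21, C10orf10 rose by 3.13 ± 0.19 and SUSD2 rose by 2.98 ± 0.26 (adjusted p of the 6 at most 2.12e-07). The largest fall was of the microRNA gene MIR30A (chromosome 6, 71403551 to 71403621), which fell by 7.93 ± 0.22, from 6641 ± 803 to 27.9 ± 10.9 RPKM (adjusted p = 1.25e-12). The vessel-destabilising factor ANGPT2 fell by 2.86 ± 0.12, and the transcription factor MESP1 fell by 3.00 ± 0.37 (adjusted p at most 8.48e-06). The small nucleolar RNA SNORD12C was listed at 0 against 6.45 ± 1.07 RPKM, SNORD43 fell by 3.52 ± 1.18 and SNORD45B fell by 3.09 ± 0.99. The SNORD43 call was lost without control 2 (adjusted p = 0.0721), control 3 (0.0608), shHIF1A 2 (0.105) or shHIF1A 3 (0.102), or with no filter (0.0547), and that of SNORD45B without control 1 (adjusted p = 0.0795), shHIF1A 1 (0.0668) or shHIF1A 3 (0.0651), or with the 3 libraries left out (0.0917).

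**Figure D3:**
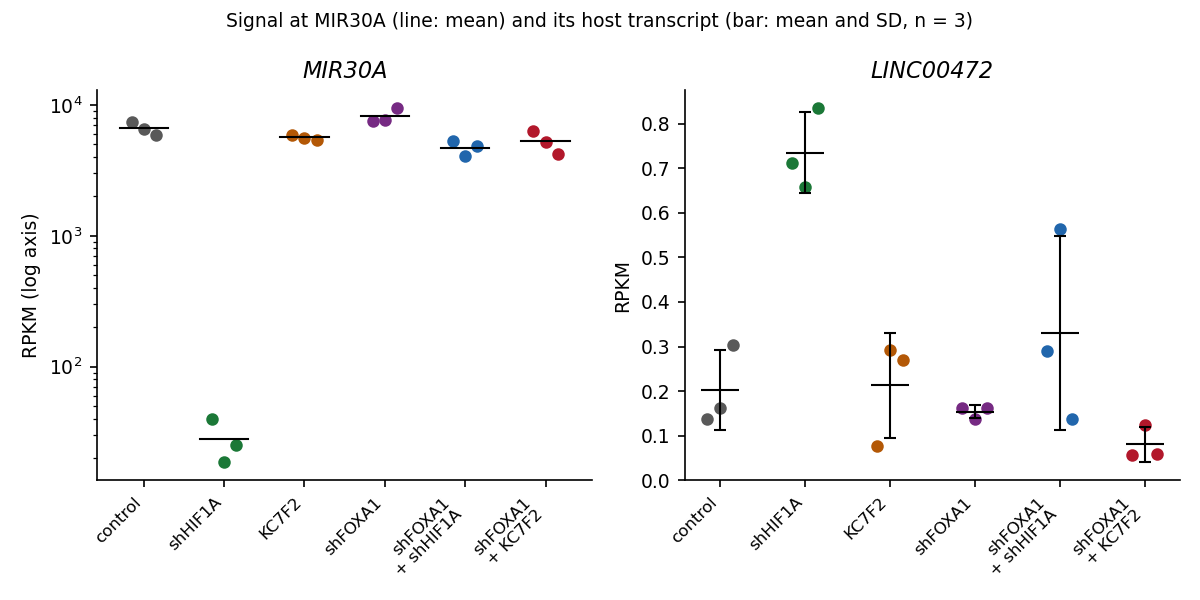
RPKM of MIR30A (log axis) and of LINC00472, the noncoding gene that holds it, in each of the 18 libraries by group. MIR30A lay between 18.5 and 39.8 RPKM in shHIF1A and above 4051 elsewhere, while LINC00472 averaged 0.735 RPKM in shHIF1A and 0.202 in control.

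Of the hypoxia targets, 6 of 34 rose and 16 fell (6 and 16 over the list alone), median -0.24, camera adjusted p = 0.00565 (adjusted p = 0.275 with an estimated correlation). PDK1, which keeps pyruvate out of the mitochondria, fell by 1.44 ± 0.09, while the carbonic anhydrase CA12 rose by 1.82 ± 0.13, and the growth factor TGFA rose by 1.38 ± 0.12. Among glycolysis enzymes, 4 of 21 rose and 11 fell (4 and 12 over the list alone), median -0.37, camera adjusted p = 0.00622 (adjusted p = 0.427 with an estimated correlation). LDHA fell by 1.67 ± 0.11, from 195 ± 17.9 to 61.1 ± 7.002 RPKM, GPI fell by 0.78 ± 0.12 and GAPDH fell by 0.85 ± 0.13 (adjusted p of these 6 at most 7.21e-05). Androgen receptor targets fell here too: 3 of 29 rose and 20 fell (5 and 21 over the list alone), median -0.72, camera adjusted p = 2.6e-10. The protease gene TMPRSS2 fell by 2.24 ± 0.09, and ACPP fell by 2.47 ± 0.10. Proliferation genes fell: 0 of 30 rose and 29 fell (0 and 29 over the list alone), median -1.42, camera adjusted p = 9.2e-21. NUSAP1 fell by 2.07 ± 0.13 and RRM2 fell by 2.27 ± 0.16. Of the p53 targets, 15 of 20 rose and 1 fell (15 and 1 over the list alone), median 0.79, camera adjusted p = 9.18e-06 (adjusted p = 0.0926 with an estimated correlation). CDKN1A rose by 2.09 ± 0.11, and the antiproliferative gene BTG2 rose by 1.25 ± 0.09. FOXA and partner transcription factors gave 0 of 9 rose and 4 fell (0 and 4 over the list alone), median -0.24, camera adjusted p = 0.047 (adjusted p = 0.346 with an estimated correlation), a call lost without control 2 (adjusted p = 0.0922), control 3 (0.145), shHIF1A 1 (0.0688) or shHIF1A 3 (0.0537), or in other settings, such as no filter (0.139). The prostate homeobox gene HOXB13 fell by 0.48 ± 0.09 and ETV1 fell by 0.43 ± 0.11.

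Interferon-stimulated genes rose: 14 of 25 rose and 0 fell (15 and 1 over the list alone), median 0.62, camera adjusted p = 0.000144. IFIT2 rose by 2.23 ± 0.19, and IFI6 rose by 2.16 ± 0.21. Of the chemokines and cytokines, 7 of 11 rose and 0 fell (8 and 0 over the list alone), median 0.65, camera adjusted p = 0.00622 (adjusted p = 0.145 with an estimated correlation), lost with 5 RPKM or more (adjusted p = 0.0552). CXCL10, a T cell attractant induced by interferon, rose by 2.12 ± 0.29, and LIF rose by 1.00 ± 0.14. Basal epithelial markers gave 4 of 6 rose and 1 fell (4 and 1 over the list alone), median 1.56, camera adjusted p = 0.0112 (adjusted p = 0.0926 with an estimated correlation), with LAMB3 1.72 ± 0.13 and the integrin ITGB4 1.86 ± 0.17. In the TGF-beta pathway, 9 of 19 rose and 0 fell (9 and 0 over the list alone), median 0.30, camera adjusted p = 0.0429 (adjusted p = 0.0926 with an estimated correlation), a call lost without control 1 (adjusted p = 0.0502), control 3 (0.0543), shHIF1A 1 (0.0868), shHIF1A 2 (0.0691) or shHIF1A 3 (0.0738), or in other settings, such as 5 RPKM or more (0.128). TGFBI rose by 1.60 ± 0.24 and SKI rose by 0.75 ± 0.13. Of the metallothioneins, 0 of 5 rose and 5 fell (0 and 5 over the list alone), median -1.20, camera adjusted p = 0.00139 (adjusted p = 0.0876 with an estimated correlation). MT1G fell by 2.03 ± 0.25 and SLC30A1 fell by 0.69 ± 0.12. NRF2 targets gave 1 of 22 rose and 9 fell (1 and 9 over the list alone), median -0.27, camera adjusted p = 0.00411 (adjusted p = 0.346 with an estimated correlation). Thioredoxin reductase TXNRD1 fell by 1.34 ± 0.09 and AKR1B10 rose by 2.11 ± 0.21. For the ATF4 and unfolded protein response, 7 of 28 rose and 11 fell (7 and 11 over the list alone), median -0.19, camera adjusted p = 0.0257 (adjusted p = 0.523 with an estimated correlation), a call lost without control 1 (adjusted p = 0.0502), or with the 3 libraries left out (0.0527). ASNS fell by 1.23 ± 0.10 and XBP1 fell by 0.86 ± 0.10. HIF1A knockdown raised 3347 genes and lowered 2075, 675 and 480 of them at least 2-fold, with 2831 and 2545 under median-ratio scaling and 2917 and 2590 under quantile normalisation.

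KC7F2 against control asked what the HIF1A inhibitor does when FOXA1 is present. The transmembrane glycoprotein GPNMB rose by 1.75 ± 0.11, the fatty acid desaturase SCD rose by 1.44 ± 0.13, and SREBF1, the regulator of fatty acid synthesis, rose by 1.35 ± 0.12. The cholesterol exporter ABCG1 rose by 1.21 ± 0.19 and ANGPT2 rose by 1.23 ± 0.12 (adjusted p of these 5 at most 0.00148). The transcription factor MAF fell by 1.76 ± 0.09, FKBP5, a cochaperone of steroid receptors, fell by 1.40 ± 0.10, STEAP4 fell by 1.42 ± 0.14, TUBA3D fell by 1.42 ± 0.21 and PI3 fell by 1.38 ± 0.21 (adjusted p at most 0.00147). The microRNA MIR8055 rose by 2.17 ± 0.46 (adjusted p = 0.0183), and MIR6776 was listed at 0 against 3.02 ± 2.55 RPKM (adjusted p = 0.0403). The MIR8055 call was lost without control 2 (adjusted p = 0.092), KC7F2 2 (0.0825) or KC7F2 3 (0.0905), or with a pseudocount of 0.1 (0.0917) or only the groups compared (0.143), and that of MIR6776 without control 1 (adjusted p = 0.0897), control 2 (0.0582), control 3 (0.069), KC7F2 1 (0.145), KC7F2 2 (0.0937) or KC7F2 3 (0.124), or in other settings, such as only the groups compared (0.0834). With only the groups compared PI3 (adjusted p = 0.145) and TUBA3D (0.0839) lost their calls. Without the 3 libraries, which left 1 KC7F2 library, ABCG1 had no call but a like change (1.18, adjusted p = 0.13).

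Several gene lists moved with KC7F2 in control cells. Of the androgen receptor targets, 0 of 29 rose and 16 fell (1 and 23 over the list alone), median -0.49, camera adjusted p = 1.93e-41. ELL2, an elongation factor, fell by 1.13 ± 0.07, and HPGD fell by 1.37 ± 0.13. NRF2 targets rose: 12 of 22 rose and 0 fell (18 and 0 over the list alone), median 0.64, camera adjusted p = 1.45e-25. OSGIN1 rose by 1.20 ± 0.13 and the quinone reductase NQO1 rose by 1.01 ± 0.12. Cholesterol synthesis genes ranked higher: 6 of 21 rose and 0 fell (11 and 0 over the list alone), median 0.38, camera adjusted p = 4.63e-09. INSIG1 rose by 1.19 ± 0.12. Hypoxia targets ranked lower: 0 of 34 rose and 5 fell (0 and 9 over the list alone), median -0.10, camera adjusted p = 5.77e-08. NDRG1 fell by 1.02 ± 0.10, and VLDLR fell by 0.62 ± 0.09. Glycolysis enzymes gave no call: 0 of 21 rose and 1 fell (0 and 1 over the list alone), median 0.12, camera adjusted p = 0.676, with a mean of 0.01 and a test direction that was down. The lactate exporter SLC16A3 fell by 0.86 ± 0.14. Lower ranks were also called for mesenchymal markers, where 0 of 10 rose and 1 fell (0 and 2 over the list alone), median -0.25, camera adjusted p = 0.000196, and for chemokines and cytokines, where 0 of 11 rose and 0 fell (0 and 2 over the list alone), median -0.30, camera adjusted p = 5.09e-05. THBS1 fell by 1.06 ± 0.14 and CCL2 was at -0.95 ± 0.28 (adjusted p = 0.105), passing without control 3 (adjusted p = 0.0109), or with trend removal (0.0338). With only the groups compared NQO1 (adjusted p = 0.0868), VLDLR (0.101), SLC16A3 (0.0817) and THBS1 (0.0817) lost their calls. With 1 KC7F2 library left, without the 3, VLDLR (-0.50, adjusted p = 0.14) and SLC16A3 (-0.96, adjusted p = 0.11) had none.

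Other calls in the KC7F2 comparison were p53 targets, where 0 of 20 rose and 1 fell (0 and 3 over the list alone), median -0.08, camera adjusted p = 0.000485 (adjusted p = 0.166 with an estimated correlation), HIF pathway regulators, where 0 of 17 rose and 0 fell (0 and 0 over the list alone), median -0.13, camera adjusted p = 0.0052 (adjusted p = 0.0612 with an estimated correlation), lost with the 3 libraries left out (adjusted p = 0.122) or the length-trend term (0.114), and basal markers, where 0 of 6 rose and 0 fell (0 and 1 over the list alone), median -0.16, camera adjusted p = 0.0163 (adjusted p = 0.0929 with an estimated correlation). The p53 call was lost without control 1 (adjusted p = 0.0758), and the basal call without control 2 (adjusted p = 0.0771) or KC7F2 3 (0.0525), or in other settings, such as the length-trend term (0.0964). The p53 target BTG2 fell by 0.34 ± 0.09 (adjusted p = 0.047), a call lost without control 2 (adjusted p = 0.134), control 3 (0.155), KC7F2 1 (0.119), KC7F2 2 (0.12) or KC7F2 3 (0.159), or in other settings, such as only the groups compared (0.416). KC7F2 raised 135 genes and lowered 128, 18 and 19 of them at least 2-fold, with 1537 at an unadjusted p below 0.05. With median-ratio scaling 101 rose and 194 fell, with quantile normalisation 105 and 172, and with only the groups compared 14 and 12. The count was 502 without control 1, 173 without control 2, 172 without control 3, 150 without KC7F2 1, 165 without KC7F2 3, 67 without the 3 libraries, where 1 KC7F2 library stood against 2, and 409 with trend removal.

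Adding the HIF1A shRNA to FOXA1 knockdown asked how much of the FOXA1-loss response needs HIF1A. The growth factor PTN rose by 5.66 ± 0.25, from 0.518 ± 0.322 to 49.2 ± 1.55 RPKM, the mesenchymal filament VIM rose by 3.33 ± 0.18, and KITLG, the ligand of the KIT receptor, rose by 3.04 ± 0.15. TMEM158 rose by 3.15 ± 0.20 and DHRS2 rose by 3.21 ± 0.26 (adjusted p of these 5 at most 9.54e-08). MIR4720 rose by 3.19 ± 0.91 (adjusted p = 0.0112), a call lost without shFOXA1 2 (adjusted p = 0.0643). WNT11 fell by 3.99 ± 0.17, S100A8 fell by 4.06 ± 0.46, and the stress keratin KRT6B fell by 4.41 ± 0.23. The lipid receptor gene S1PR3 fell by 3.68 ± 0.14, and SNORD36B fell by 3.82 ± 0.60 (adjusted p of these 5 at most 0.00011). CCL2 fell by 1.93 ± 0.28, from 17.3 ± 4.14 to 4.13 ± 0.627 RPKM, VEGFA fell by 0.86 ± 0.14, and KLK3 fell by 1.08 ± 0.13 (adjusted p at most 0.000127). CA9 was listed at 0.

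The hypoxia programme fell when HIF1A was depleted on top of FOXA1. Of the hypoxia targets, 3 of 34 rose and 21 fell (4 and 22 over the list alone), median -0.59, camera adjusted p = 3.47e-11. PDK1 fell by 2.48 ± 0.09, PFKFB4 fell by 2.13 ± 0.10, and the collagen-modifying enzyme PLOD2 fell by 2.69 ± 0.18. Among glycolysis enzymes, 1 of 21 rose and 16 fell (2 and 17 over the list alone), median -1.05, camera adjusted p = 4.88e-12 (adjusted p = 0.0892 with an estimated correlation). LDHA fell by 2.59 ± 0.11, ENO2 fell by 1.61 ± 0.11 and phosphofructokinase PFKP fell by 1.51 ± 0.12 (adjusted p of these 6 at most 9.9e-08). Androgen receptor targets gave 9 of 29 rose and 14 fell (10 and 15 over the list alone), median -0.38, camera adjusted p = 0.00235 (adjusted p = 0.102 with an estimated correlation). MAF fell by 1.696 ± 0.09, TMPRSS2 fell by 1.74 ± 0.09, and FKBP5 fell by 1.76 ± 0.10. Proliferation genes fell further: 1 of 30 rose and 21 fell (1 and 24 over the list alone), median -0.74, camera adjusted p = 6.06e-11. NUSAP1 fell by 1.38 ± 0.13 and RRM2 fell by 1.63 ± 0.16. Of the p53 targets, 16 of 20 rose and 1 fell (16 and 1 over the list alone), median 0.85, camera adjusted p = 4.62e-06 (adjusted p = 0.102 with an estimated correlation). CDKN1A rose by 1.69 ± 0.11, and BTG2 rose by 1.22 ± 0.09. The metallothionein list gave 0 of 5 rose and 3 fell (0 and 3 over the list alone), median -0.66, camera adjusted p = 0.0106 (adjusted p = 0.141 with an estimated correlation), with MT1G -2.002 ± 0.25 and MT1F -1.32 ± 0.33. In all, 3096 genes rose and 1745 fell, 546 and 456 at least 2-fold. Median-ratio scaling gave 2257 and 2358, shifting the median of all genes from 0.10 to -0.01, and quantile normalisation gave 2531 and 2294.

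KC7F2 given to FOXA1 knockdown cells asked the same with the inhibitor. KRT16 fell by 3.17 ± 0.17, S100A8 fell by 3.13 ± 0.46, PI3 fell by 2.58 ± 0.21, and KRT6B fell by 2.44 ± 0.23 (adjusted p at most 0.000605). SNORA71A fell by 2.81 ± 0.46 and MIR6126 fell by 2.74 ± 0.55, a call lost with only the groups compared (adjusted p = 0.0697). GPNMB rose by 2.29 ± 0.11. The other large rises were small RNA genes. MIR7112 rose by 4.17 ± 1.01 (adjusted p = 0.0268), and SNORD100, SNORD21, MIR6777 and MIR6132 were listed at 0 without the inhibitor and at 6.11 ± 6.42, 4.85 ± 3.43, 2.98 ± 1.72 and 2.40 ± 1.58 RPKM with it (adjusted p at most 0.0386). These calls rested on few libraries: without shFOXA1 1, 2 and 3 and shFOXA1 plus KC7F2 1, 2 and 3 in turn, adjusted p was under 0.05, 0.105, 0.113, 0.0799, 0.104 and 0.0602 for MIR7112, 0.0815, 0.0752, 0.0823, 0.0511, under 0.05 and 0.134 for SNORD100, 0.104, 0.1, 0.106, 0.108, under 0.05 and 0.16 for SNORD21, and 0.0684, 0.0648, 0.0689, 0.104, 0.0582 and under 0.05 for MIR6777. Without a filter or with robust eBayes the first 3 were lost as well. CCL2 stood at 9.17 ± 1.98 against 17.3 ± 4.14 RPKM, a change of -0.88 ± 0.28 (adjusted p = 0.097). VEGFA was at -0.02 ± 0.14 (adjusted p = 0.969), and KLK3 at 0.00 ± 0.13 (adjusted p = 0.997).

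By list, NRF2 targets rose with KC7F2 in FOXA1 knockdown cells: 15 of 22 rose and 0 fell (18 and 0 over the list alone), median 0.77, camera adjusted p = 2.8e-30. The cystine transporter SLC7A11 rose by 1.54 ± 0.11, and OSGIN1 rose by 1.48 ± 0.13. Cholesterol synthesis genes ranked higher: 6 of 21 rose and 0 fell (7 and 0 over the list alone), median 0.29, camera adjusted p = 1.29e-09. INSIG1 rose by 1.20 ± 0.12. Hypoxia targets ranked lower: 0 of 34 rose and 6 fell (0 and 9 over the list alone), median -0.23, camera adjusted p = 1.07e-06 (adjusted p = 0.0517 with an estimated correlation). PDK1 fell by 0.66 ± 0.09, and NDRG1 fell by 0.55 ± 0.10. Among glycolysis enzymes, 0 of 21 rose and 4 fell (0 and 8 over the list alone), median -0.26, camera adjusted p = 1.26e-07 (adjusted p = 0.109 with an estimated correlation). LDHA fell by 0.64 ± 0.11. Chemokines and cytokines ranked lower: 0 of 11 rose and 5 fell (0 and 9 over the list alone), median -0.88, camera adjusted p = 6.47e-08. CXCL10 fell by 1.79 ± 0.29 and CXCL8 fell by 1.25 ± 0.23. Of the p53 targets, 0 of 20 rose and 6 fell (0 and 9 over the list alone), median -0.25, camera adjusted p = 2.79e-08. BTG2 fell by 0.63 ± 0.09 and the death receptor FAS fell by 0.91 ± 0.15. Androgen receptor targets gave 2 of 29 rose and 9 fell (4 and 12 over the list alone), median -0.26, camera adjusted p = 1.17e-05, with MAF -0.92 ± 0.09 and ELL2 -0.69 ± 0.07. Basal markers gave 0 of 6 rose and 3 fell (0 and 3 over the list alone), median -0.50, camera adjusted p = 2.5e-05, with COL17A1 -1.55 ± 0.18 and LAMB3 -0.70 ± 0.13.

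Calls that 1 library could end were those for mesenchymal markers, where 0 of 10 rose and 0 fell (0 and 2 over the list alone), median -0.31, camera adjusted p = 0.024 (adjusted p = 0.103 with an estimated correlation), lost without shFOXA1 1 (adjusted p = 0.058), or in other settings, such as 5 RPKM or more (0.373), the interferon response, where 0 of 25 rose and 2 fell (0 and 2 over the list alone), median -0.19, camera adjusted p = 0.03 (adjusted p = 0.115 with an estimated correlation), lost without shFOXA1 2 (adjusted p = 0.0783) or shFOXA1 plus KC7F2 1 (0.0615), or in other settings, such as 5 RPKM or more (0.145), and the heat shock response, where 0 of 17 rose and 2 fell (0 and 3 over the list alone), median -0.11, camera adjusted p = 0.0139 (adjusted p = 0.351 with an estimated correlation), lost without shFOXA1 plus KC7F2 2 (adjusted p = 0.0807), or with quantile normalisation (0.101). The interferon regulator IRF1 fell by 0.84 ± 0.11 (adjusted p = 0.00016). KC7F2 raised 220 genes and lowered 306 in these cells, 45 and 78 at least 2-fold, with 257 and 370 under median-ratio scaling and 325 and 372 under quantile normalisation. The count was 303, 350 and 317 without shFOXA1 1, 2 and 3, 329, 312 and 311 without shFOXA1 plus KC7F2 1, 2 and 3, and 855 with trend removal.

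Reversal of the FOXA1-loss response was then counted gene by gene. Of the 1228 genes higher after FOXA1 knockdown, 480 fell when HIF1A was also depleted (39.1%, against 166 for independent lists), and of the 1883 lower genes 711 rose (37.8%, against 452). With KC7F2, 188 of the higher genes fell (15.3%, against 29.1) and 68 of the lower genes rose (3.61%, against 32.1). Leaving out replicate 1, 2 or 3 of every group gave 323, 291 and 297 and 383, 284 and 469 with HIF1A knockdown, and 67, 30 and 52 and 25, 6 and 16 with KC7F2. Median-ratio scaling gave 637 and 483 with HIF1A knockdown and 215 and 62 with KC7F2. In 100 simulations with no effect, or none of HIF1A inhibition, sharing shFOXA1 libraries alone gave at most 1. For 33 hypoxia and glycolysis genes higher after FOXA1 knockdown (median 0.64), adding the HIF1A shRNA lowered 28 and raised 2, with a median of -1.16, while KC7F2 lowered 9, with a median of -0.28. Choosing these genes without 1 shFOXA1 library and measuring against that library alone, a test added after the data were seen, gave -1.18, -1.14 and -1.22, and -0.30, -0.36 and -0.29 with KC7F2. LDHA went from 351 ± 9.39 RPKM in shFOXA1 to 58.0 ± 7.70 with the HIF1A shRNA and 225 ± 4.50 with KC7F2. It was 195 ± 17.9 in control and 61.1 in shHIF1A.

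**Figure D4:**
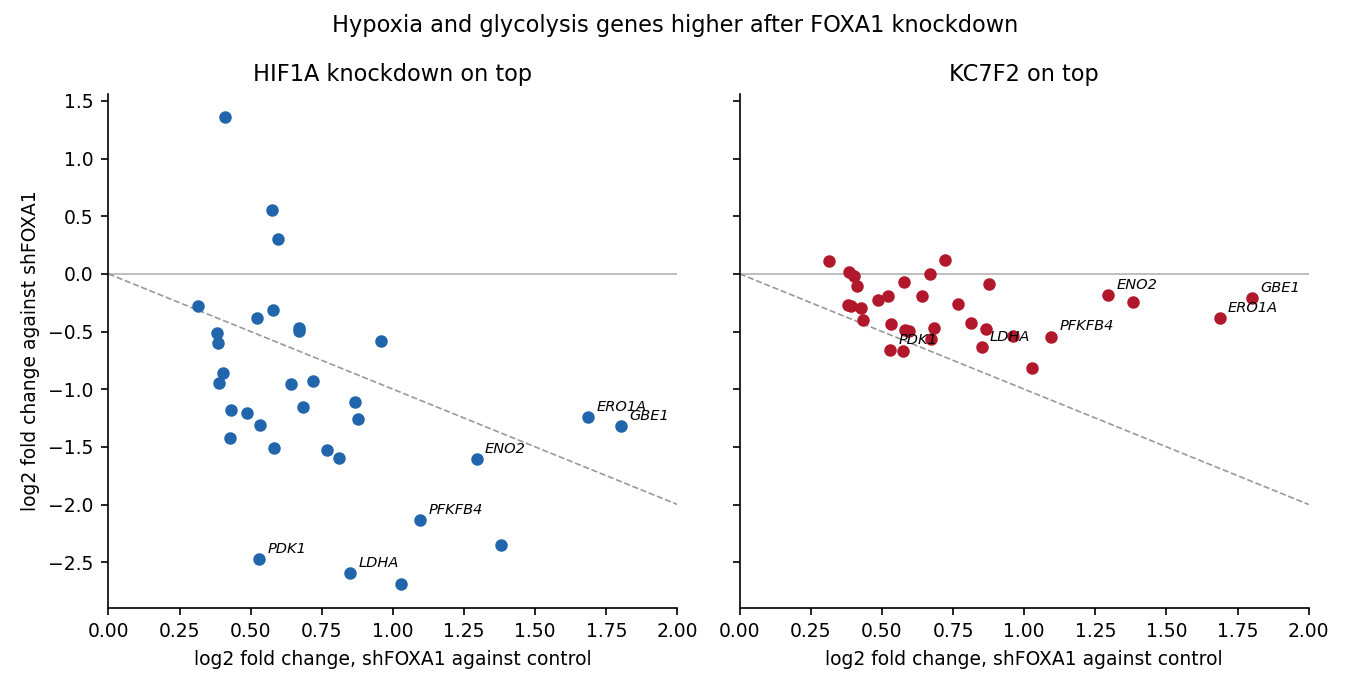
Log2 fold change of 33 hypoxia and glycolysis genes after FOXA1 knockdown (x axis) against the change when HIF1A knockdown (left) or KC7F2 (right) was added (y axis), with full reversal as a dashed line. In each panel 30 of 33 lay below 0, with medians of -1.16 and -0.28.

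FOXA1 knockdown in HIF1A-depleted cells asked which FOXA1 effects stand without HIF1A. MIR30A rose by 7.44 ± 0.22, from 27.9 ± 10.9 to 4729 ± 631 RPKM, and reads from a vector stay open as the source. PTN rose by 4.44 ± 0.25, TMEM158 rose by 3.78 ± 0.20, KRT16 rose by 3.59 ± 0.17, and the hair keratin KRT36 rose by 3.21 ± 0.20. SNORD116-18 was listed at 0 in shHIF1A and at 4.54 ± 1.77 RPKM in the doubly infected cells (adjusted p of these 6 at most 0.00568). TARP fell by 2.55 ± 0.21, and ADAM7 fell by 2.28 ± 0.15. SNORD1B and MIR630 were listed at 0, against 2.44 ± 1.45 and 2.25 ± 0.501 RPKM. SNORA52 fell by 2.74 ± 0.84 and SNORD76 fell by 2.72 ± 0.67. The SNORA52 call was lost without shHIF1A 2 (adjusted p = 0.11), shHIF1A 3 (0.117), shFOXA1 plus shHIF1A 1 (0.119) or shFOXA1 plus shHIF1A 2 (0.136), or in other settings, such as no filter (0.0747), and that of SNORD76 without shHIF1A 1 (adjusted p = 0.0508). CCL2 rose by 1.11 ± 0.28, from 1.64 ± 0.285 to 4.13 ± 0.627 RPKM (adjusted p = 0.0119), a call lost without shHIF1A 2 (adjusted p = 0.0536). VEGFA was at -0.37 ± 0.14 (adjusted p = 0.0815), passing without shHIF1A 3 (adjusted p = 0.0167) or shFOXA1 plus shHIF1A 2 (0.0349), and KLK3 at -0.33 ± 0.13 (adjusted p = 0.108), passing with quantile normalisation (-0.23, adjusted p = 0.048).

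Hypoxia targets gave no call without HIF1A: 2 of 34 rose and 7 fell (3 and 8 over the list alone), median -0.15, camera adjusted p = 0.35. ERO1A rose by 1.15 ± 0.11, and NDRG1 fell by 0.69 ± 0.10. Among glycolysis enzymes, 0 of 21 rose and 4 fell (1 and 7 over the list alone), median -0.21, camera adjusted p = 0.033 (adjusted p = 0.712 with an estimated correlation), a call lost without shHIF1A 1 (adjusted p = 0.119), shHIF1A 2 (0.0833), shFOXA1 plus shHIF1A 2 (0.156) or shFOXA1 plus shHIF1A 3 (0.0609), or with 5 RPKM or more (0.0527) or trend removal (0.167). Androgen receptor targets ranked lower: 5 of 29 rose and 13 fell (6 and 15 over the list alone), median -0.31, camera adjusted p = 0.00887 (adjusted p = 0.161 with an estimated correlation), lost with 5 RPKM or more (adjusted p = 0.0527). SLC45A3 fell by 1.89 ± 0.13. Proliferation genes fell: 0 of 30 rose and 20 fell (1 and 22 over the list alone), median -0.65, camera adjusted p = 2.68e-09. RRM2 fell by 1.32 ± 0.16 and survivin BIRC5 fell by 1.37 ± 0.16. Basal markers rose: 4 of 6 rose and 0 fell (4 and 0 over the list alone), median 1.02, camera adjusted p = 0.000107. KRT14 rose by 2.05 ± 0.22 and LAMB3 rose by 1.07 ± 0.13. NRF2 targets ranked higher: 10 of 22 rose and 0 fell (11 and 1 over the list alone), median 0.37, camera adjusted p = 2.45e-08 (adjusted p = 0.112 with an estimated correlation). SLC7A11 rose by 1.04 ± 0.11, and GCLC rose by 0.82 ± 0.09. The interferon response ranked lower: 0 of 25 rose and 9 fell (1 and 9 over the list alone), median -0.33, camera adjusted p = 0.00277 (adjusted p = 0.0701 with an estimated correlation). IFI6 fell by 1.82 ± 0.21, and IFIT1 fell by 1.39 ± 0.23.

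Calls under HIF1A knockdown that 1 library could end included mesenchymal markers, where 4 of 10 rose and 2 fell (5 and 4 over the list alone), median 0.26, camera adjusted p = 0.0438 (adjusted p = 0.184 with an estimated correlation), lost without shHIF1A 1 (adjusted p = 0.0531), shHIF1A 3 (0.0549), shFOXA1 plus shHIF1A 1 (0.126), shFOXA1 plus shHIF1A 2 (0.267) or shFOXA1 plus shHIF1A 3 (0.284), or in other settings, such as trend removal (0.106). THBS1 rose by 1.89 ± 0.14 and VIM rose by 1.73 ± 0.18. Cholesterol synthesis gave 0 of 21 rose and 3 fell (0 and 3 over the list alone), median -0.18, camera adjusted p = 0.0347 (adjusted p = 0.536 with an estimated correlation), lost without shHIF1A 2 (adjusted p = 0.0586) or shFOXA1 plus shHIF1A 2 (0.156), or with 5 RPKM or more (0.0569), and HMGCS1 fell by 0.76 ± 0.09. Of the p53 targets, 4 of 20 rose and 2 fell (5 and 2 over the list alone), median 0.10, camera adjusted p = 0.0178 (adjusted p = 0.497 with an estimated correlation), lost without shFOXA1 plus shHIF1A 1 (adjusted p = 0.0714), and MDM2 rose by 0.55 ± 0.09. In all, 680 genes rose and 1193 fell, 167 and 154 at least 2-fold, with 804 and 973 under median-ratio scaling and 898 and 1023 under quantile normalisation. The count was 1230 without shHIF1A 1 and 1174 without shHIF1A 2.

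FOXA1 knockdown in KC7F2-treated cells repeated the contrast under the inhibitor. RGS4, a brake on G protein signalling, rose by 4.45 ± 0.15, from 0.274 ± 0.0880 to 16.3 ± 0.435 RPKM, S1PR3 rose by 3.75 ± 0.14, and the acute-phase gene SAA1 rose by 3.57 ± 0.20. PI3 rose by 3.64 ± 0.21, S100A9 rose by 3.498 ± 0.20 and WNT11 stood at 5.39 ± 0.910 RPKM from a level listed at 0 (adjusted p of these 6 at most 3.16e-09). TARP fell by 4.31 ± 0.21, S100P fell by 3.502 ± 0.34, NUDT8 fell by 3.35 ± 0.21, the decarboxylase DDC fell by 3.13 ± 0.18 and UGT2B11 fell by 2.89 ± 0.16 (adjusted p at most 9.92e-07). CCL2 rose by 3.01 ± 0.28, from 0.717 ± 0.345 to 9.17 ± 1.98 RPKM, and VEGFA rose by 0.63 ± 0.14 (adjusted p = 0.00247), a call lost with the 3 libraries left out (0.61, adjusted p = 0.062). KLK3 was at 0.30 ± 0.13 (adjusted p = 0.0937), and was called higher with median-ratio scaling (0.48, adjusted p = 0.0027), quantile normalisation (0.70, adjusted p = 3.72e-06) and trend removal (0.51, adjusted p = 0.0012).

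Hypoxia targets ranked higher under KC7F2 as well: 16 of 34 rose and 1 fell (17 and 1 over the list alone), median 0.31, camera adjusted p = 2.12e-08. ERO1A rose by 1.30 ± 0.11 and VLDLR rose by 0.95 ± 0.09. Among glycolysis enzymes, 7 of 21 rose and 3 fell (7 and 3 over the list alone), median 0.12, camera adjusted p = 0.0131 (adjusted p = 0.506 with an estimated correlation), with GBE1 1.44 ± 0.13 and ENO2 0.98 ± 0.11. HIF pathway regulators gave 4 of 17 rose and 1 fell (4 and 1 over the list alone), median 0.21, camera adjusted p = 0.0131 (adjusted p = 0.107 with an estimated correlation), lost with trend removal (adjusted p = 0.135) or the 3 libraries left out (0.109), with CITED2 0.73 ± 0.10. Oxidative phosphorylation genes ranked lower: 0 of 29 rose and 19 fell (0 and 21 over the list alone), median -0.59, camera adjusted p = 6.95e-05 (adjusted p = 0.481 with an estimated correlation). ATP5B fell by 0.64 ± 0.10 and NDUFA9 fell by 0.59 ± 0.12, with more signal in short genes in KC7F2 1 and 3. Androgen receptor targets gave no call: 5 of 29 rose and 15 fell (5 and 16 over the list alone), median -0.37, camera adjusted p = 0.164, but called with no filter (adjusted p = 0.0137). ACPP fell by 2.61 ± 0.10, whereas FKBP5 rose by 2.09 ± 0.10. Proliferation genes fell: 0 of 30 rose and 30 fell (0 and 30 over the list alone), median -1.34, camera adjusted p = 3.39e-18. NUSAP1 fell by 1.74 ± 0.13 and BIRC5 fell by 1.98 ± 0.16. Basal markers rose: 4 of 6 rose and 0 fell (4 and 0 over the list alone), median 1.56, camera adjusted p = 5.61e-06. LAMB3 rose by 2.51 ± 0.13 and COL17A1 rose by 1.73 ± 0.18.

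Of the chemokines and cytokines, 6 of 11 rose and 0 fell (6 and 1 over the list alone), median 0.59, camera adjusted p = 0.000124 (adjusted p = 0.0515 with an estimated correlation), with CXCL2 2.004 ± 0.23. Mesenchymal markers gave 4 of 10 rose and 2 fell (4 and 3 over the list alone), median 0.25, camera adjusted p = 0.0152 (adjusted p = 0.107 with an estimated correlation), lost with median-ratio scaling (adjusted p = 0.0751), quantile normalisation (0.128) or only the groups compared (0.0593), with THBS1 2.31 ± 0.14. The TGF-beta pathway gave 6 of 19 rose and 2 fell (6 and 2 over the list alone), median 0.13, camera adjusted p = 0.00371, lost with 5 RPKM or more (adjusted p = 0.0858), with ID2 1.18 ± 0.10. NRF2 targets gave 9 of 22 rose and 1 fell (9 and 1 over the list alone), median 0.18, camera adjusted p = 0.000269 (adjusted p = 0.273 with an estimated correlation), with HMOX1 2.04 ± 0.15. Cholesterol synthesis gave 0 of 21 rose and 11 fell (0 and 11 over the list alone), median -0.39, camera adjusted p = 0.00976 (adjusted p = 0.333 with an estimated correlation), lost with 5 RPKM or more (adjusted p = 0.053) or quantile normalisation (0.111), with SC5D -0.53 ± 0.10, a call lost with the 3 libraries left out (-0.41, adjusted p = 0.0508). Under KC7F2, 1145 genes rose and 3105 fell, 313 and 414 at least 2-fold. Median-ratio scaling gave 1921 and 1762 and quantile normalisation 1712 and 1822, moving the median of all genes from -0.15 to 0.02 and -0.02. The count was 2813 without KC7F2 1 and 1788 without the 3 libraries.

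Across the 12900 genes, which are not independent replicates, FOXA1 knockdown changes in control and HIF1A-depleted cells had r = 0.42, those in control and KC7F2-treated cells r = 0.75, and the remaining pair r = 0.44, with no shared libraries. Of 369 genes at least 2-fold higher after FOXA1 knockdown, 160 rose and 10 fell under HIF1A knockdown, and their median went from 1.52 to 0.49, whereas 316 rose under KC7F2, with a median of 1.26. Of 324 genes at least 2-fold lower, 177 fell and 4 rose under HIF1A knockdown, with medians of -1.27 and -0.64, and 292 fell under KC7F2, with a median of -1.27. Choosing genes by their change in control cells by itself lowers their medians in other backgrounds.

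Whether FOXA1 effects differed between backgrounds was tested as an interaction. With HIF1A knockdown 982 genes passed, 408 with a more positive and 574 with a more negative FOXA1 effect, and 2721 had an unadjusted p below 0.05. With KC7F2 10 genes passed, 2 and 8, and 872 had an unadjusted p below 0.05. That count ranged from 2 without control 2 to 23 without control 1, and was 3 with a pseudocount of 0.1 and 27 with 1. The smallest adjusted p values with HIF1A knockdown were those of ENC1 (-2.65 ± 0.12), MIR30A (7.13 ± 0.31), WNT11 (-4.13 ± 0.24), ACPP (2.24 ± 0.15), PI3 (-4.46 ± 0.30) and the calpain CAPN2 (-1.73 ± 0.12), at most 4.45e-07. Among hypoxia targets, 0 of 34 were higher and 13 lower (0 and 21 over the list alone), median -0.53, camera adjusted p = 7.48e-12, and among glycolysis enzymes, 0 of 21 were higher and 11 lower (0 and 15 over the list alone), median -0.60, camera adjusted p = 7.48e-12. For chemokines and cytokines, 0 of 11 were higher and 6 lower (0 and 9 over the list alone), median -1.58, camera adjusted p = 5.35e-08. Androgen receptor targets ranked more positive: 11 of 29 were higher and 4 lower (13 and 5 over the list alone), median 0.30, camera adjusted p = 0.000118, as did proliferation genes: 11 of 30 were higher and 0 lower (16 and 0 over the list alone), median 0.61, camera adjusted p = 2.87e-10. With KC7F2, the androgen receptor targets had the smallest camera p: 1 of 29 were higher and 0 lower (13 and 0 over the list alone), median 0.41, camera adjusted p = 1e-23. For hypoxia targets, 0 of 34 were higher and 0 lower (2 and 1 over the list alone), median -0.08, camera adjusted p = 0.881, with a mean of -0.06, an upward test direction and a median of 0.01 under median-ratio scaling. Among glycolysis enzymes, 0 of 21 were higher and 0 lower (0 and 0 over the list alone), median -0.36, camera adjusted p = 1.84e-06 (adjusted p = 0.282 with an estimated correlation). KRT16 had -3.22 ± 0.24 and ENC1 -1.22 ± 0.12 (adjusted p at most 7.2e-05).

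HIF1A knockdown and KC7F2 were compared as genetic and chemical inhibition of the same protein. Their changes had r = 0.17 across genes in control cells, where sharing the control libraries alone gave 0.50 in simulated data and a covariance of 0.0302 against 0.0308 observed. In FOXA1 knockdown cells r was 0.30, with a covariance of 0.0648 against 0.0305 simulated. Between backgrounds, where no library is shared, r was -0.02 and 0.11. Of 176 genes called in both comparisons in control cells 72 went in opposite directions, and in FOXA1 knockdown cells 92 of 343 did. ANGPT2 is an example: it fell by 2.86 ± 0.12 with the HIF1A shRNA and rose by 1.23 ± 0.12 with KC7F2. TXNRD1 fell by 0.94 ± 0.09 with the HIF1A shRNA in FOXA1 knockdown cells and rose by 0.90 ± 0.09 with KC7F2. KC7F2 effects in control and FOXA1 knockdown cells had r = 0.28, with 75 genes higher in both (2.302 for independent lists), 60 lower in both (3.04) and 1 opposite.

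Few markers of other cell types could be tested. Of the fixed lists, 2 fibroblast markers could be tested, led by COL1A1 at 3.30 RPKM over all libraries, 1 leukocyte marker, CD68 at 9.59 RPKM, and 1 endothelial marker, VWF at 0.918 RPKM. Of 22 neuroendocrine markers 3 could be tested, led by SYT4 at 621 RPKM. The 13 mitochondrially encoded mRNAs were not analysed here, and these 5 lists were too short to test.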

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

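The tests on MIR30A, the spread for opposite directions, the length and GC trend removal and leaving out the 3 libraries were chosen after the data were seen, the other tests before.

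Each result here came from an interaction term in limma, which asks whether the FOXA1 knockdown effect differed with HIF1A knockdown or KC7F2. With HIF1A knockdown 982 genes passed. Of 100 orders of the additive model's residuals, only the real one gave as many. The highest other gave 87, which argues against chance among these libraries, but not between cultures. With KC7F2 10 genes passed (2 to 32 in other settings) and 3 of 100 orders gave as many. The highest gave 803, which points to a structure among these libraries, so chance stays open.

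ENC1 rose by 4.39 ± 0.08 after FOXA1 knockdown in control cells and by 1.74 ± 0.08 under HIF1A knockdown, an interaction of -2.65. WNT11 had 4.44 ± 0.17 and 0.31 ± 0.17, an interaction of -4.13. PI3 had 4.84 ± 0.21 and 0.38 ± 0.21, an interaction of -4.46, with 3.25 ± 0.21 for the HIF1A shRNA alone. CAPN2 had 1.89 ± 0.09 and 0.16 ± 0.09, an interaction of -1.73. ACPP had -2.46 ± 0.10 and -0.22 ± 0.10, an interaction of 2.24. HIF1A itself had 1.9995 ± 0.23 and 0.26 ± 0.23, an interaction of -1.74, and the shRNA against it was present in the latter. With KC7F2, KRT16 had 6.25 ± 0.17 in control cells and 3.03 ± 0.17 under the inhibitor, an interaction of -3.22. ENC1 had -1.22, NRCAM -1.37, S100A9 -1.62, MAF 0.84 and ENDOD1 0.66. These calls were lost, with adjusted p in brackets, for MAF without any of 6 libraries (0.0814 without KC7F2 1), NRCAM without any of 11 libraries (0.115 without shFOXA1 plus KC7F2 2), S100A9 without any of 11 libraries (0.122 without shFOXA1 plus KC7F2 3) and ENDOD1 without any of 11 libraries (0.135 without shFOXA1 plus KC7F2 2) and in other settings, such as a pseudocount of 0.1 for NRCAM (0.215) and S100A9 (0.119), quantile normalisation for ENDOD1 (0.0996) and only the groups compared for MAF (0.0648).

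For gene lists the interaction with HIF1A knockdown had a median of -0.53 in hypoxia targets, -0.60 in glycolysis enzymes, -1.58 in chemokines and cytokines, -1.14 in basal markers, -0.44 in the interferon response, -0.25 in the TGF-beta pathway and -0.23 in HIF pathway regulators (adjusted p = 0.0828 with an estimated correlation). It was 0.61 in proliferation genes, 0.30 in androgen receptor targets, 0.25 in oxidative phosphorylation (adjusted p = 0.6 with an estimated correlation) and 0.24 in NRF2 targets (adjusted p = 0.43 with an estimated correlation). The oxidative phosphorylation call was lost without control 1 (adjusted p = 0.241) or the 3 libraries (0.204). That of regulators, HIF1A included, was lost with trend removal (0.0563) and that of the TGF-beta pathway with 5 RPKM or more (0.235). With KC7F2 the median was 0.41 in androgen receptor targets, -0.36 in glycolysis enzymes, -0.36 in chemokines and cytokines, -0.33 in basal markers, -0.26 in the heat shock response, -0.26 in p53 targets, -0.25 in oxidative phosphorylation, 0.16 in replication histones and 0.13 in NRF2 targets. Of these 9 calls only that for androgen receptor targets held with an estimated correlation, and the others had adjusted p = 0.282 with an estimated correlation, or 0.78 for oxidative phosphorylation. Leaving out single libraries ended 4 of these calls: chemokines for 4 libraries (highest adjusted p = 0.0889, without control 3), histones for 6 libraries (highest adjusted p = 0.628, without control 3), basal markers for 6 libraries (highest adjusted p = 0.337, without shFOXA1 3) and oxidative phosphorylation for 8 libraries (highest adjusted p = 0.662, without control 3). Each was also lost in at least 1 other setting.

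MIR30A fell by 7.93 ± 0.22 with the HIF1A shRNA alone and returned in the doubly infected cells, an interaction of 7.13. Lower HIF1A as the sole cause is argued against by the doubly infected cells, where HIF1A stood at 4.32 ± 0.245 RPKM and MIR30A differed from shFOXA1 by -0.80 ± 0.22. Reads from the miR-30 hairpin of pGIPZ stay open. Control had 6641 RPKM of MIR30A but 0.202 of LINC00472, the gene that holds it. LINC00472 differed by 0.82 ± 0.16 (0.66 to 0.99) in shHIF1A but could fall by at most 0.48, so its change decides nothing. The backbone of the HIF1A shRNA is not stated. A different one would enter every contrast with this shRNA, the 982 interaction genes and its reversal counts included. A second infection may enter those with both shRNAs.

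The response to FOXA1 knockdown was smaller under HIF1A knockdown, where FOXA1 mRNA was left at 53.8%, against 36.0% in control cells, a difference that did not pass (adjusted p = 0.142). A weaker knockdown would shrink every change without turning it, and 6.81 ± 1.13% of the 999 genes called in both backgrounds went in opposite directions, and 5.83 to 7.49% with each of the 12 libraries left out. That is above the bound of 5% by more than the SE, but a 95% interval (4.19 to 9.42) reaches below it. A different backbone in the shHIF1A libraries would also enter this share. It therefore does not decide whether a weaker knockdown is the whole cause. Dependence on HIF1A fits for the hypoxia and glycolysis genes: the median of the 33 that had risen was -0.08 under HIF1A knockdown, at percentile 0 of 10000 matched sets of other risen genes, which also shrank, from 0.63 to 0.19, so a weaker knockdown as part of the cause stays open.

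Oxidative phosphorylation genes ranked lower after FOXA1 knockdown while control 1 carried more signal in short genes. Removing each library's trend on gene length and GC content moved the median of the 26 annotated genes to -0.24 (-0.41 to -0.07), from -0.31 for all 29, and the list call held (adjusted p = 0.0083). Bias of this kind and a fall caused by FOXA1 loss cannot be told apart, since the range, from a standard error over libraries of 0.17, reaches above the bound of -0.1, and the call was lost without control 1 (adjusted p = 0.134) or the 3 libraries (0.106).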

How the results depend on the processing

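Removal of the length and GC trend, leaving out small RNA genes, the length-trend term and leaving out 3 libraries together were tests chosen after the data were seen. No result changed direction with a call on both sides. For 271 genes and contrasts printed, 165 of 4802 alternative values changed the call (152 lost and 13 gained), and for 103 lists 214 of 2158 did (209 lost and 5 gained). The interaction count with KC7F2, of 10 genes, became 3 with a pseudocount of 0.1, 27 with 1, 27 without a filter, 25 with quantile normalisation, 3 with only the groups compared, 32 with the trend removed, 24 without small RNA genes and 2 without the 3 libraries. With only the groups compared, FOXA1 knockdown gave 1747 genes and KC7F2 26, where fewer libraries estimate the spread. With the length and GC trend removed KC7F2 gave 409 and KC7F2 after FOXA1 knockdown 855, and the length-trend term gave KC7F2 300 genes. Without the 3 libraries, which leaves 1 KC7F2 library assumed to vary like the other groups, KC7F2 gave 67 and FOXA1 knockdown under KC7F2 1788. The correlation of FOXA1 effects in control and HIF1A knockdown cells was 0.39 with a pseudocount of 0.1, 0.39 without a filter and 0.48 at 5 RPKM or more, that in control and KC7F2 cells 0.67 and 0.83 with the lower pseudocount and the stricter filter, and that in the inhibited backgrounds 0.49 with the stricter filter. With an estimated correlation 38 list calls held of 92. Where no construction is named, the cause was not tested.

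Leaving out 1 library at a time gave 2260 to 3938 genes for FOXA1 knockdown, 4454 to 5239 for HIF1A knockdown, 150 to 502 for KC7F2, 3993 to 4257 for HIF1A knockdown and 303 to 350 for KC7F2 added to FOXA1 knockdown, 1174 to 1646 and 2813 to 4320 for FOXA1 knockdown under HIF1A knockdown and KC7F2, 691 to 1207 for the interaction with HIF1A knockdown, and 2 (without control 2) to 23 (without control 1) for that with KC7F2. Single libraries that moved a count more than 1.5 times were control 1, control 2, control 3, KC7F2 1, KC7F2 3 in the count for KC7F2; shFOXA1 1, shFOXA1 2, shFOXA1 3, shFOXA1 plus KC7F2 1, shFOXA1 plus KC7F2 2, shFOXA1 plus KC7F2 3 in the count for KC7F2 after FOXA1 knockdown; shHIF1A 1, shHIF1A 2 in the count for FOXA1 knockdown under HIF1A knockdown; KC7F2 1 in the count for FOXA1 knockdown under KC7F2; control 1, control 2, control 3, shFOXA1 1, shFOXA1 3, KC7F2 1, KC7F2 2, KC7F2 3, shFOXA1 plus KC7F2 1, shFOXA1 plus KC7F2 2, shFOXA1 plus KC7F2 3 in the count for interaction of FOXA1 knockdown and KC7F2. FOXA1 mRNA ranged from -1.68 to -1.35 and HIF1A mRNA from 1.68 to 2.17 after FOXA1 knockdown, from -2.81 to -2.32 after HIF1A knockdown and from -4.29 to -4.15 where both were depleted. Leaving out 1 replicate number in every group gave 291 to 323 reversed higher genes and 284 to 469 reversed lower genes with HIF1A knockdown, and 30 to 67 and 6 to 25 with KC7F2. Correlations of FOXA1 effects ranged over 0.36 to 0.41, 0.64 to 0.74 and 0.37 to 0.43, and those of HIF1A knockdown with KC7F2 over 0.17 to 0.28 in control cells, 0.29 to 0.34 in FOXA1 knockdown cells, and -0.0488 to 0.0349 and 0.0410 to 0.13 between backgrounds. Replicate numbers did not pair the libraries: 45 residual correlations of the same number ran from -0.21 to 0.25, and 9 of 18 libraries matched best with their own number. As a block they gave 3342, 5561, 287, 4943, 556, 1995, 4452, 1039 and 9 genes in the order of the contrasts, with calls gained for KLK3 after FOXA1 knockdown (adjusted p = 0.0255) and FOXA1 knockdown under KC7F2 (0.0474), and lost for BTG2 and MIR6776 with KC7F2 (0.0507 each) and, in the interaction with KC7F2, S100A9 (0.0605), basal markers (0.053) and histones (0.0556).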

Other observations

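The tests of the splits below were chosen before the results were seen, and the genes described here were chosen after their values were seen.

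Replication histone genes went both ways when HIF1A was depleted on top of FOXA1: 5 of 14 rose and 3 fell (5 and 4 adjusted over the list alone), with no camera call (adjusted p = 0.675). The linker histone HIST1H1C rose by 1.47 ± 0.20, from 74.7 ± 11.98 to 207 ± 16.8 RPKM, and HIST1H3B fell by 1.93 ± 0.43. Interferon genes had no list call either (adjusted p = 0.297), though IFIT2 rose by 1.19 ± 0.19 and IFIT3 rose by 1.27 ± 0.24.

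Redox genes split in the same contrast. SLC7A11 rose by 1.77 ± 0.11, from 15.2 ± 1.16 to 53.1 ± 1.04 RPKM, and AKR1B10 rose by 2.13 ± 0.21, while HMOX1 fell by 1.80 ± 0.15, from 89.5 ± 9.51 to 25.3 ± 1.67 RPKM. The NRF2 list had no call (adjusted p = 0.305). PGK1, a glycolytic kinase, stood at 421 ± 78.1 RPKM in shHIF1A against 229 ± 35.6 in control, and EPAS1 at 2.12 ± 0.214 RPKM against 0.914 ± 0.148.

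Other splits of the 6 libraries of a contrast into 3 and 3 were fitted in the same way, and 10 splits are too few for a share under 0.05. The real split gave 3111 genes for FOXA1 knockdown and the highest other 3, and 5422 and 0 for HIF1A knockdown. For HIF1A knockdown and KC7F2 added to FOXA1 knockdown these were 4841 and 2, and 526 and 2. For FOXA1 knockdown under HIF1A knockdown and KC7F2 they were 1873 and 3, and 4250 and 0. In each of these 1 of the 10 splits, the real one, gave as many genes. For KC7F2 in control cells 2 of 10 did: the real split gave 263 and another 2479. That split sets control 1 and KC7F2 1 and 3, with more signal in short genes, against the rest, which points to a structure of the samples, and a term for it gave 300 genes for KC7F2.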
